A study of Mus musculus with 2 samples.

How the data were processed

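Total RNA of 2 sorted fractions of a mouse bone marrow DC culture was measured on Agilent whole-genome arrays of 1 design. Per the labels' protocols, 0.5 µg of RNA was amplified and labelled with Cy3, so each array has 1 colour and holds 1 sample. The group of each array, CD103+ or CD103−, was taken from the sample labels. There was 1 array per group, and both arrays lay on 1 slide. The number of arrays limits the precision, and no replicate check of any difference was possible.

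Per the file headers, the deposited spot intensity values were extracted with Agilent Feature Extraction 10.7.3.1, which subtracted background and corrected spatial trends within each array. The submitters' processing notes name version 9.1 of that program, and the difference between the versions was not resolved. The values were not normalized between arrays. The deposited table of the whole series held the same intensity on a linear scale, neither logged nor centred: probes with 1 spot had the scanner value of the same array to within a relative difference of 1.2e-06. How repeated spots were combined there is not given in the sources used here. Its direction needs no settling, because each column is 1 array. The median of its columns was 69.4 for the CD103+ array and 90.5 for the CD103− array.

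The log2 of the processed signal was taken, and each array's 75th percentile over probes that were not controls was subtracted. That percentile was an intensity of 1256 on the CD103+ array and 1506 on the CD103− array. Control spots and spots flagged as non-uniform or as population outliers were left out, and the remaining spots of a probe were averaged. No spot was saturated. Of 39429 probes, 27234 matched 1 gene symbol, 0 matched several and 12195 matched none, by accession without version against a RefSeq gene table of the mouse assembly GRCm38.p6. The file headers name another build, so no genome coordinates are given. For a gene with several probes, the probe with the highest mean signal over both arrays stood for the gene. A gene was counted if that probe was well above background on at least 1 array. Where it was not on the other array, its value there was the higher of its own signal and the lowest signal well above background on that array, which was −6.51 on the CD103+ array and −6.63 on the CD103− array, and the difference is a bound. Another 22 genes had no value because their bound was under 1-fold.

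The log2 difference was compared with a fixed size rule of 2-fold, with no test. Error estimates came from the scanner software's error of each spot and were nearly the same for bright genes, so they are not spreads measured gene by gene. The median estimate over 13831 genes was 0.204. The median SD of the difference was 0.075 between repeated spots of 259 probes and 0.108 between probes of 3521 genes. Between probes of a gene its 90th percentile was 0.434, so probes of some genes differ by more than the error estimate. None of these measures covers differences between cultures. Median differences of 33 gene lists were set among 10000 random lists of the same size, drawn from 20 bins of mean signal, and a list stood apart below the 2.5 or above the 97.5 percentile. The percentile describes these 2 arrays only. The lists, the size rule and the rule for named genes were fixed before the data were examined. The lists were cDC1, cDC2, pan-DC, monocyte and macrophage, plasmacytoid DC, neutrophil, mast cell and basophil, eosinophil, B cell, T and NK cell, erythroid and megakaryocyte, progenitor, stromal and endothelial, DC maturation, MHC class II pathway, MHC class I and cross-presentation, Toll-like receptor, cytokine, chemokine, chemokine receptor, retinoic acid and tolerance, DC transcription factors, cell cycle, interferon-stimulated, GM-CSF and Flt3 signalling, integrin, C-type lectin, Fc receptor and apoptotic cell uptake, lysosomal protease, glycolysis, cholesterol synthesis, control and sex-linked genes. Several genes stand in more than 1 list. Of the listed genes, 15 had no usable probe with their name.

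The rule named a set of lineage genes always, the 10 genes with the largest difference each way among genes above background on both arrays, the 5 with the largest bound each way among genes above background on 1 array, and the list members with the largest differences past 2-fold. Symbols of predicted or clone genes were passed over, and some genes that the rule picked are not reported here. Other list members named were picked as examples after their values were seen, and the genes named outside the patches likewise.

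Patches of the array surface were sought after the values were seen. A spot was taken as a patch core if at least 3 of its 12 nearest spots were at least 8-fold different in the same direction or flagged non-uniform on either array, and its 12 nearest spots were added. There were 829 cores, against a mean of 123 and a highest count of 168 in 100 permutations of the spots. The patch spots numbered 2890. Because the rule picks such spots, their share in patches is not a test of crowding, and the kind of the 12 nearest spots was compared with 100 permutations instead. For a count of flagged spots, areas were set by the same rule from spots at least 8-fold lower alone, without flags.

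Alternatives were normexp background correction (limma 3.58.1, offset 50, on median spot and background signals, a departure from the plan, which had named mean spot signals), scaling on the median, quantile normalization, a percentile over probes above background on both arrays, the deposited series table, other filters on dim probes, the mean over a gene's probes, size rules of 1.5-fold and 3-fold, and random lists not matched on expression. Leaving the patches out and scaling on the spike-in controls were added after the data were seen. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and R 4.3.3. The steps were tested on simulated data made from the arrays' own signals. For the size rule and the lists, the mean of both arrays was given independent noise close to the scanner software's median error estimate. No simulated gene had a bound, and none lay in a patch. With so little noise the counts of these 2 steps were nearly fixed in advance. They check the calculation and do not show how often the rules err on real arrays. Over 13831 genes, the size rule found 100 of 100 genes planted with a log2 difference of 1.5, 100 of 100 planted with 3 and 0 unplanted genes. Of 100 lists of genes drawn at random with no shift, 6 stood apart, and of 20 such lists shifted by 0.5, 20 did. Lists of genes that vary together were not simulated. The patch step found 82 of 92 spots of a planted track among 39283 probes and marked 1024 others.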

Results

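Gene expression was measured in dendritic cells (DCs) grown from the bone marrow of C57BL/6 mice in a culture that induces cells bearing CD103, an integrin chain that marks a subset of DCs. Cells that carried the DC integrin CD11c and lacked B220, a surface marker of B cells and plasmacytoid DCs, had been sorted into a fraction with high CD103 and a fraction without it. Each fraction was hybridised to 1 array, so the series held 2 arrays and no replicates, and no p-value could be given for any difference. Differences below are log2 signal of the CD103+ cells minus that of the CD103− cells. The value after ± is the scanner software's error estimate of that difference. It was 0.204 alike for bright genes such as Itgax, Batf3 and Irf8. The estimate is therefore not a spread measured over each gene's spots, and it does not cover the cells. On the CD103+ array 64.4% of 43020 spots were well above background, against 66.5% on the CD103− array. A gene that was well above background on 1 array only has a bound, written as "at least", which rests on the background correction used.

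The comparison asked how the transcripts of CD103+ DCs differ from those of CD103− DCs of the same culture. The CD103+ cells had far more signal for genes of the cross-presenting conventional DC type 1 (cDC1), and the CD103− cells had more for genes of conventional DC type 2 (cDC2), monocytes and macrophages. Clec9a, a receptor for actin exposed on dead cells, was higher in the CD103+ cells by 10.45 ± 0.31, or 1398-fold. The signal of Clec9a in the CD103− cells was dim, at −6.08, so the size of the fold is uncertain, and normexp gave a log2 difference of 8.31. Irf8, a transcription factor needed for cDC1 development, was 10.6-fold higher in the CD103+ cells (3.40 ± 0.20). Sirpa, an inhibitory receptor of cDC2 and macrophages, was 16.0-fold lower in them, and Irf4, a transcription factor of cDC2, was 8.69-fold lower (−3.12 ± 0.20).

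Of 15067 genes with a value, 953 were at least 2-fold higher and 1626 at least 2-fold lower in the CD103+ cells. With a background correction by normexp, a model of signal plus background, and an added offset of 50, the counts were 671 higher and 1034 lower. Folds of genes dim in 1 fraction were smaller, so normexp values are given beside several of them. An offset draws differences of dim genes toward 0 by construction, and median processed signals were 74.3 on the CD103+ and 98.4 on the CD103− array. How much of each change came from the offset was not tested. At 8-fold, 128 genes were higher and 324 lower. Across 13831 genes well above background on both arrays the log2 signals correlated with r = 0.955, a value across genes, which are not independent replicates. Other probes were compared only for the 783 higher and 1246 lower genes well above background on both arrays, and only where those probes were so too. Of 179 other probes of higher genes 93.3%, and of 270 of lower genes 90.7%, differed in the same direction. By at least 2-fold in that direction it was 68.7% and 67.4% of the other probes. Patches of the array surface, found after the values were seen, held 6.72% of the spots. Outside them 845 genes were higher and 1442 lower of 14258, and at 8-fold 92 were higher and 238 lower.

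Of 21 measured cDC1 genes, 17 were at least 2-fold higher in the CD103+ cells and 0 lower. Their median difference was 2.93, above all 10000 random lists of the same size matched on expression (percentile 100), a description of these 2 arrays. Tlr3, an endosomal sensor of viral RNA, was at least 135-fold higher, and Xcr1, the receptor for the chemokine Xcl1, at least 39.3-fold. Neither was well above background in the CD103− cells, and the size of such differences of dim genes depends on how background is handled and on any offset. With normexp the log2 difference was 4.77 for Tlr3, 3.05 for Xcr1 and 8.31 for Clec9a. Gcsam was at least 219-fold higher (5.25 with normexp), and Cadm1, an adhesion molecule, differed by 6.72 ± 0.23 (5.44 with normexp). Rab7b, a small GTPase of late endosomes, differed by 6.35 ± 0.20, Clnk by 4.96 ± 0.32 and Snx22 by 4.60 ± 0.21. Wdfy4, which is needed for cross-presentation of cell-associated antigen, was 3.98-fold higher. The 4 members inside 2-fold were Batf3, Cd24a, Jaml and Ly75, the last dim and from a spot in or beside a patch. Batf3, a transcription factor required for cDC1 development, had nearly the same log2 signal in both fractions (3.71 and 3.69 above the 75th percentile, difference 0.02 ± 0.20), and the sign of its difference turned negative with 3 of the 10 other settings.

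Of 20 cDC2 genes, 12 were at least 2-fold lower in the CD103+ cells and 1 higher, with a median of −1.97 (percentile 0). Clec4a3 was 40.4-fold lower, Tmem176b 7.17-fold and Csf1r, the receptor for the macrophage growth factor M-CSF, 5.08-fold. With normexp Clec4a3 had −4.39. Clec4a4 differed by −3.91 ± 0.21, and Clec4a1 was 15.7-fold lower from a spot in or beside a patch. Cd209a, the gene of a DC-SIGN family lectin, was the higher one, by 1.21 ± 0.20. Itgam, the gene of CD11b, differed by −0.57 ± 0.20 on its brightest probe, but its 3 probes ranged from −2.82 to −0.57. Mgl2, Esam, Notch2 and Klf4 were within 2-fold.

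Of 25 monocyte and macrophage genes, 21 were at least 2-fold lower in the CD103+ cells and 0 higher, with a median of −3.76 (percentile 0) that came to −2.86 with normexp. The chains of complement C1q were lower by a large margin, C1qa 42.7-fold, C1qb 23.0-fold and C1qc 35.9-fold. Mrc1, the mannose receptor, was 27.1-fold lower. Mertk, a receptor for apoptotic cells, was 21.5-fold lower, Cx3cr1, the receptor for fractalkine, 17.5-fold, and Adgre1, the gene of F4/80, 14.2-fold. With normexp the difference was −4.14 for C1qa, −4.46 for C1qc and −2.38 for Mertk. The lysozyme gene Lyz1 was 242-fold lower from a spot in or beside a patch, and Lyz2, outside the patches, 3.37-fold lower. Fcgr1, the gene of CD64, and Apoe were within 2-fold, with −0.61 ± 0.20 and −0.45 ± 0.20.

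The plasmacytoid DC genes went both ways. Of 17 measured, 9 were at least 2-fold lower in the CD103+ cells and 1 higher, with a median of −1.06 (percentile 0) that came to −0.59 with normexp. Klk1 was 24.8-fold lower, Blnk 20.3-fold, Ly6d 18.0-fold and Cox6a2 10.8-fold. Spib and Tcf4, transcription factors of plasmacytoid DCs, were 3.76-fold and 2.55-fold lower. Ccr9, a gut-homing chemokine receptor, was 21.5-fold higher. With normexp the differences were −3.84 for Klk1, −2.89 for Ly6d and 3.32 for Ccr9. Siglech, a plasmacytoid DC receptor, was well above background on both arrays, with a log2 signal of 6.32 in CD103+ and 6.07 in CD103− cells.

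**Figure D1:**
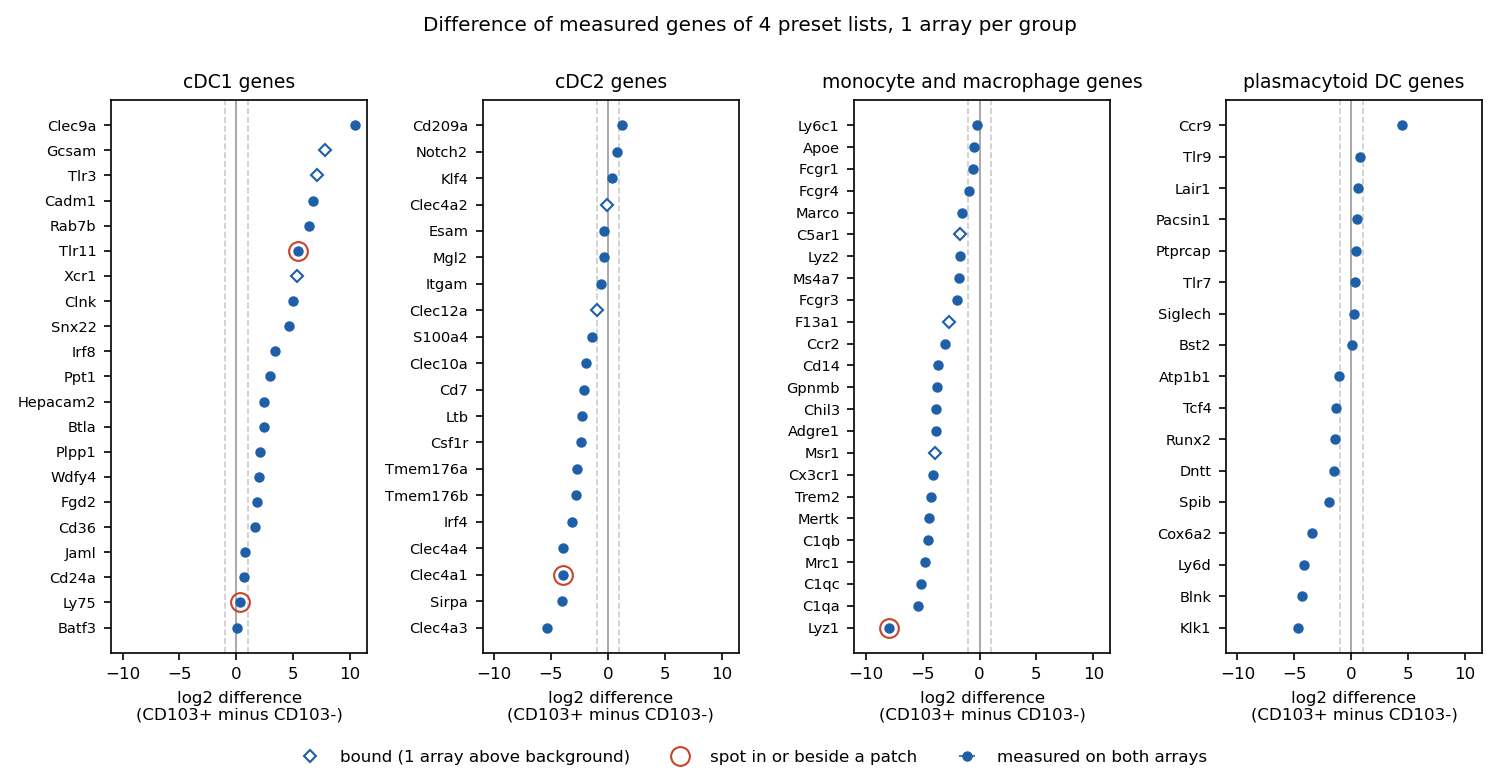
Log2 difference (CD103+ minus CD103−) of measured genes of the cDC1, cDC2, monocyte and macrophage, and plasmacytoid DC lists, with 1 array per group. Filled points were measured on both arrays, with bars, mostly smaller than the points, for the scanner's error estimate. Open diamonds are bounds, red circles mark spots in or beside a patch and dashed lines 2-fold. The cDC1 genes lie from 0.02 (Batf3) to 10.45 (Clec9a), and the monocyte and macrophage genes shown all lie below 0.

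Genes shared by all conventional DCs differed less. Of 13 pan-DC genes, 2 were at least 2-fold higher in the CD103+ cells and 1 lower, with a median of 0.53 (percentile 99.9). Flt3, the receptor for the DC growth factor Flt3 ligand, was 3.75-fold higher and Dpp4, the gene of CD26, 2.36-fold. Itgax, the gene of CD11c, differed by −0.61 ± 0.20, Zbtb46, a transcription factor of conventional DCs, by 0.78 ± 0.20, and Ptprc, the gene of CD45 and B220, by 0.16 ± 0.20. No probe carried the name Itgae, the gene of CD103, in the gene table used, so the sort marker itself was not analysed here by name.

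Among the 10 genes with the largest positive difference were Sema4f, a semaphorin, with 7.50 ± 0.30, the kinase gene Dapk2 with 7.02 ± 0.21 and the protease inhibitor gene Ctla2a with 6.74 ± 0.29. Its near-identical neighbour in sequence, Ctla2b, differed by 9.41 ± 0.23 from a spot in or beside a patch, and the paralogs may share signal. Tlr12 differed by 6.39 ± 0.20, Vwa1 by 5.56 ± 0.24 and Rgs9, a regulator of G protein signalling, by 5.94 ± 0.30, although the lowest of its 3 probes gave 1.73. Clec9a, Cadm1 and Rab7b made up the rest. Among genes above background in the CD103+ cells only, Pianp was at least 136-fold higher, the Wnt receptor gene Fzd1 at least 57.7-fold and Cd40lg, from a spot in or beside a patch, at least 50.4-fold. With normexp the differences were 5.50 for Sema4f, 6.30 for Dapk2, 4.82 for Ctla2a, 8.15 for Ctla2b and 4.11 for Vwa1. It gave 4.82 for Pianp, 3.71 for Fzd1, 3.70 for Cd40lg and 3.95 for Rgs9.

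Of the 10 genes with the largest negative difference, 8 had their spot in or beside a patch. Among them were Hmg20b (−9.29), Lyz1 (−7.92), Slc37a4 (−7.44), Hat1 (−6.40), Elp2 (−6.38) and Piga (−5.43). Another probe of Hat1 gave −0.26, and normexp gave −7.62 for Hmg20b, −5.18 for Slc37a4, −5.40 for Elp2 and −3.61 for Piga. The 2 genes outside the patches were C1qa and Clec4a3. The 5 genes with the largest bound among those above background in the CD103− cells only also had their spots there. Among them were Cd6 (at least 255-fold lower), Acaa1b (175-fold), Tmem86a (146-fold) and Lad1 (123-fold), and another probe of Cd6 gave −1.23. With normexp the differences of Acaa1b, Tmem86a and Lad1 were −4.98, −4.66 and −4.61. In a list drawn outside the patches, chosen after the values were seen, the lowest genes after C1qa and Clec4a3 were Sirpb1b (−5.28 ± 0.23), the lipoprotein lipase gene Lpl (−5.24 ± 0.20), Rasgrp1 (−5.18 ± 0.24) and C1qc (−5.16 ± 0.21). The kallikrein genes Klk1b11, Klk1b27 and Klk1b24, with −5.09, −5.07 and −4.95, are near-identical paralogs and their values are uncertain, and Pla2g7 had −5.01 ± 0.21. With normexp Sirpb1b had −4.07, Klk1b27 −4.0, Rasgrp1 −3.86 and Pla2g7 −4.11. On the higher side the list added Rtl8b with 5.06 ± 0.20 and Pmepa1 with at least 49.6-fold. Among genes above background in the CD103− cells only, it gave Prkca (at least 23.5-fold lower), Egln3 (21.2-fold), Rufy4 (18.2-fold), Pld1 (17.4-fold) and the scavenger receptor gene Msr1 (15.5-fold). These bounds did not hold with normexp, whose offset draws differences of dim genes toward 0 by construction. The normexp values were −2.30 for Prkca, −2.22 for Egln3, −2.01 for Rufy4, −1.83 for Pld1, −2.04 for Msr1 and 3.37 for Pmepa1.

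**Figure D2:**
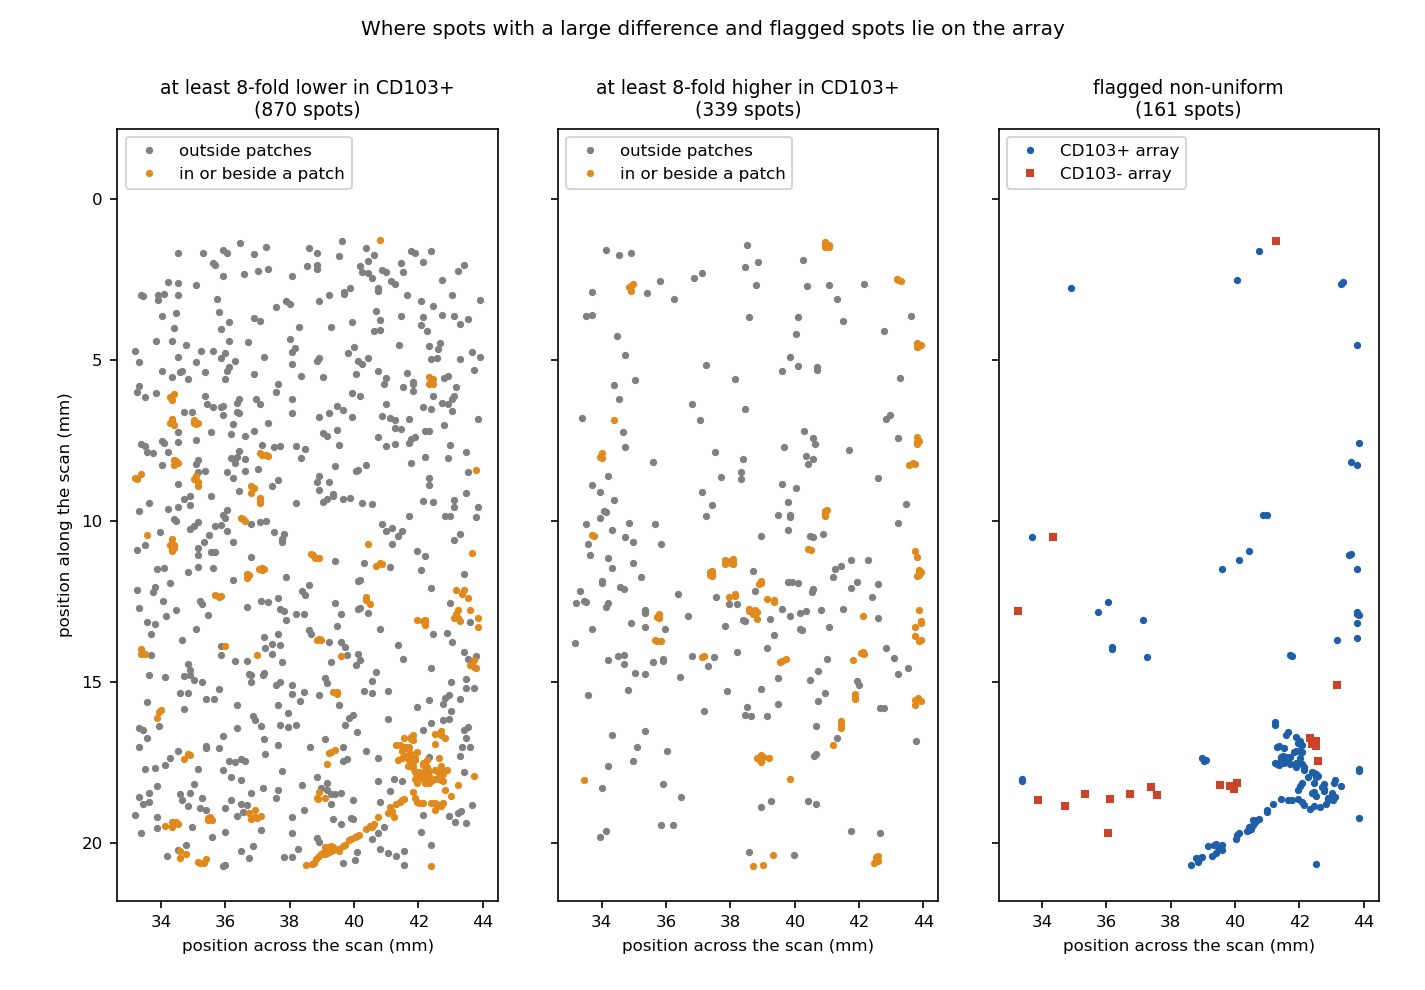
Position on the array, in mm along and across the scan, of spots at least 8-fold lower in the CD103+ cells (870), at least 8-fold higher (339) and flagged non-uniform by the scanner software. In the first and second panels orange marks the spots in or beside a patch (266 lower and 122 higher). The third panel shows the 141 flagged spots of the CD103+ array in blue and the 21 of the CD103− array in red, the blue ones crowding near the bottom right.

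Antigen presentation genes were mostly within 2-fold. Of 13 MHC class II pathway genes, 2 were at least 2-fold higher in the CD103+ cells and 1 lower, with a median of 0.39 (percentile 99.3, or 91.6 with quantile normalization, where the median was 0.14). H2-Ob, a modulator of peptide loading, was 4.11-fold higher, and Ifi30, a thiol reductase of the lysosome, 2.31-fold lower. Of 20 MHC class I and cross-presentation genes, 4 were higher and 1 lower, with a median of 0.34 (percentile 99.2, or 96.6 with normexp). Rab43, a small GTPase used in cross-presentation, was 3.98-fold higher, and the peptide transporter genes Tap2 and Tap1 2.87-fold and 2.51-fold. Cybb, the catalytic chain of the phagocyte NADPH oxidase, was 14.0-fold lower (−3.15 with normexp). Of 19 lysosomal protease genes, 6 were lower and 1 higher, with a median of −0.69 (percentile 0). The cathepsin genes Ctsd and Ctsl were 5.38-fold and 4.34-fold lower and Cst7, a cathepsin inhibitor, 10.9-fold, while Ctse was 3.57-fold higher (1.83, or 1.08 with normexp).

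Genes of pathogen and dead-cell recognition went in both directions. Of 15 Toll-like receptor genes, 4 were at least 2-fold higher in the CD103+ cells and 4 lower, with a median of 0.37 (percentile 99.3, or 96.6 with quantile normalization). Beside Tlr3, the profilin sensors Tlr12 and Tlr11 were 84.1-fold and 44.1-fold higher, Tlr11 from a spot in or beside a patch (4.78 with normexp). Tlr2, a sensor of bacterial lipoproteins, was 6.17-fold lower, Ly96 4.14-fold and Tlr4, the endotoxin receptor that Ly96 serves, 2.62-fold. Of 22 C-type lectin genes, 3 were higher and 11 lower, with a median of −1.28 (percentile 0) that came to −2.0 over genes above background on both arrays. Clec4e, a receptor for mycobacterial glycolipid, was 17.2-fold lower. Of 20 Fc receptor and apoptotic cell uptake genes, 5 were higher and 9 lower, with a median of −0.94 (percentile 0) that came to −0.48 with normexp. The phosphatidylserine receptor genes Timd4 and Havcr2 were higher, Timd4 at least 41.1-fold and Havcr2, measured on both arrays, 26.0-fold. Itgb5 differed by −3.91 ± 0.21. With normexp the differences were 3.25 for Timd4 and −3.31 for Itgb5.

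Maturation, chemokine and chemokine receptor genes were mostly lower in the CD103+ cells. Of 25 DC maturation genes, 17 were at least 2-fold lower and 1 higher, with a median of −1.37 (percentile 0). Socs2, an inhibitor of cytokine signalling, was 5.79-fold lower, and Pdcd1lg2, the gene of PD-L2, 5.34-fold, while Laptm4b was 3.12-fold higher. Of 15 chemokine genes, 13 were lower and 0 higher, with a median of −2.18 (percentile 0) that came to −1.58 with normexp. Ccl2, which attracts monocytes, was 16.7-fold lower and Ccl24 14.4-fold, with −3.42 for Ccl2 and −2.16 for Ccl24 by normexp. Of 19 cytokine genes, 9 were lower and 2 higher, with a median of −0.62 (percentile 0.02) that came to −0.33 with normexp. Csf1, the gene of M-CSF, was 16.3-fold lower, Vegfa 10.8-fold, and Tnfsf4, from a spot in or beside a patch, at least 29.7-fold. With normexp the differences were −2.12 for Csf1, −2.44 for Vegfa and −2.58 for Tnfsf4. The genes of Il16 and Il18 were 2.81-fold and 2.79-fold higher. Of 15 chemokine receptor genes, 4 were higher and 9 lower, with a median of −1.30 (percentile 0) that came to −0.73 with normexp. Cxcr3, a receptor for interferon-induced chemokines, was 20.1-fold higher (4.33, or 3.02 with normexp) and Cxcr4 8.09-fold lower (−3.02, or −2.37 with normexp).

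Of 30 DC transcription factors, 13 were at least 2-fold lower in the CD103+ cells and 3 higher, with a median of −0.74 (percentile 0). Beside Irf8, the higher ones were Id2, which cDC1 need, at 2.93-fold and Bcl6 at 2.82-fold. Zeb2 was 25.8-fold lower and Gfi1 14.4-fold, with −1.76 for Gfi1 by normexp and −3.40 for Zeb2 as a mean over its probes. The interferon-stimulated genes split. Of 23, 12 were lower and 4 higher, with a median of −1.13 (percentile 0) that came to −0.62 with normexp. Rtp4 was 10.2-fold lower and Oas1a 8.32-fold, and Ddx58, from a spot in or beside a patch, 11.9-fold. Without the patches Ddx58 rests on another probe, with a bound of −1.66. In the other direction Oasl1 was 4.88-fold and Ifi44 4.24-fold higher, with 1.13 for Ifi44 by normexp. Of 13 integrin genes, 5 were higher and 3 lower, with a median of 0.43 (percentile 99.5) that came to 0.20 (percentile 78.9) as a mean over all probes of a gene. Itga1 was 5.98-fold higher, Itga4 was 3.37-fold lower and Itgb7, the partner chain of CD103, differed by 1.63 ± 0.20. Of 13 retinoic acid and tolerance genes, 2 were higher and 2 lower, with a median of 0.21 (percentile 79.4). Aldh1a2, a retinoic acid synthesis enzyme, was 30.5-fold lower and Ido1, a tryptophan-degrading enzyme, 14.0-fold higher, both from spots in or beside a patch, and normexp gave 2.05 for Ido1.

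Genes of other lineages that a bone marrow culture can hold were, where they differed, mostly lower in the CD103+ cells. Of 16 neutrophil genes, 9 were at least 2-fold lower and 0 higher, with a median of −1.09 (percentile 0) that came to −0.55 with normexp. The collagenase gene Mmp8 was 27.2-fold lower and Prtn3 4.12-fold, while Cxcr2, from a spot in or beside a patch, was at least 10.4-fold lower, or −1.43 with normexp, which gave −4.16 for Mmp8. Of 9 mast cell and basophil genes, 5 were lower and 0 higher, with a median of −1.13 (percentile 1.15) that came to −0.73 (percentile 2.93) over genes above background on both arrays and to −0.57 with normexp. Cpa3, a mast cell protease, was 4.64-fold lower, with −1.46 by normexp. Of 9 eosinophil genes, 5 were lower and 0 higher, with a median of −1.03 (percentile 0.88) that came to −0.42 with normexp. Siglecf, an eosinophil and macrophage lectin, was 14.8-fold lower (−3.30 with normexp). Of 10 progenitor genes, 7 were lower and 1 higher, with a median of −1.75 (percentile 0). Sox4 was 7.31-fold lower (−2.25 with normexp) and Cd34 2.45-fold higher. Of 7 erythroid and megakaryocyte genes, 3 were lower and 1 higher, with a median of −0.26 (percentile 15.2) that came to −1.24 (percentile 1.18) outside the patches and to −0.08 with normexp. Pf4, a platelet chemokine, was 8.55-fold lower (−2.15 with normexp) and Itga2b 5.18-fold higher.

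Most lymphoid and stromal genes lay within 2-fold. Of 11 T and NK cell genes, 1 was at least 2-fold higher in the CD103+ cells and 2 lower, with a median of 0.41 (percentile 98.2, or 95.2 with quantile normalization) and a mean of 0.06. Tbx21, the gene of T-bet, was 9.05-fold higher and Cd2 13.8-fold lower, with 2.48 for Tbx21 and −1.71 for Cd2 by normexp. Of 8 B cell genes, 1 was lower and 0 higher, with a median of −0.33 (percentile 13.7) that came close to 0 with normexp. The lower one was Cd79b, 12.2-fold, from a spot in or beside a patch. Of 6 stromal and endothelial genes, 1 was higher and 1 lower. Their median of −0.05 (percentile 37.2) and mean of 0.05 differed in sign, and the median turned positive with 4 of the alternatives. Pecam1, the gene of CD31, was 3.79-fold higher and Sparc 2.98-fold lower, although normexp gave −0.45 for Sparc.

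Cell cycle genes and most metabolic genes were nearly level. All 25 cell cycle genes lay within 2-fold, with a median of 0.12 (percentile 52.8). Mki67, a marker of dividing cells, differed by 0.25 ± 0.20 and Top2a by 0.02 ± 0.20. All 21 cholesterol synthesis genes lay within 2-fold, with a median of −0.15 (percentile 0.63, or 3.43 among random lists not matched on expression). Of 20 glycolysis genes, 1 was higher and 2 lower, and the median of 0.08 (percentile 23.9) and mean of −0.06 differed in sign. Of 14 GM-CSF and Flt3 signalling genes, 2 were higher and 2 lower, and here too the median of 0.08 (percentile 31.0) and mean of −0.06 differed in sign. Flt3 (3.75-fold higher) and Socs2 (5.79-fold lower) lay farthest apart, and Ccnd1, the gene of cyclin D1, was 2.47-fold higher and Stat5a 2.39-fold lower. The glycolysis and signalling medians turned negative with quantile normalization. All 15 control genes lay within 2-fold, with a median of 0.22 (percentile 72.5), as did 4 sex-linked genes, with a median of 0.10 (percentile 55.6). Across alternatives these medians near 0 ran from 0.04 to 0.25 for cell cycle, from −0.25 to −0.02 for cholesterol synthesis, from 0.02 to 0.35 for control and from 0.03 to 0.23 for sex-linked genes. In all, 24 of the 33 lists stood outside the central 95% of their random lists, where 1.65 would be expected for lists of genes that vary independently. Genes of a list can vary together, and some lists share genes, so the count is not a test of significance.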

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

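All tests in this part were chosen after the result they bear on was seen.

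The scanner software flagged 141 spots of the CD103+ array as non-uniform, against 21 on the CD103− array, a signal outside the measurements that the comparison used. Spots at least 8-fold lower in the CD103+ cells crowded together, as 4.97% of their 12 nearest spots were of the same kind, against at most 2.74% in 100 permutations. Areas set by the lower spots alone held 0% of the flagged spots of the CD103− array, against 68 of the 141 of the CD103+ array (Fisher's exact test, p = 4.97e-06). This argues against damage in these areas that gets spots of the CD103− array flagged. The flagged spots crowd together and the test takes them as independent, so its p-value can overstate the difference. Dimming of the CD103− array would make spots higher in the CD103+ cells, which areas set this way cannot show. A real difference in all of the genes with lower spots in the patches is argued against by their other probes elsewhere. Of these, 36.2% of 58 were at or below −1, against 27 of 36 for genes whose lower spot lay outside the patches (Fisher's exact test, p = 0.000304). The 58 probes covered only 49 of 183 genes with a lower spot in the patches, and several genes had more than 1. This test and the interval below take probes as independent, so both can overstate the precision. Genes outside also needed a lower probe well above background on both arrays, which was not asked of genes in the patches. Local damage that dims spots of the CD103+ array is a candidate explanation of the lower spots there, since the other probes had a median of −0.33 (bootstrap 95% interval −0.66 to −0.02), but 21 of the 58 were low as well, so some of these genes may differ between the cells. Dimming alone would not make the spots at least 8-fold higher, which crowded too (5.60% against at most 1.23%), and their genes' other probes were too few to decide, with 7 of 13 at or above 1 against 10 of 12 for genes outside (Fisher's exact test, p = 0.202).

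The plasmacytoid DC genes parted, with Klk1, Blnk, Ly6d and Cox6a2 far lower in the CD103+ cells, Ccr9 21.5-fold higher and several others near equal. Klk1 belongs to the tissue kallikrein family, whose near-identical paralogs can share signal on probes. Plasmacytoid DCs left in the CD103− fraction are a candidate source, although the sort against B220 would remove most of them. Their abundant genes should then be lower in the CD103+ cells too, but the 3 brightest members, Siglech (0.25), Pacsin1 (0.51) and Bst2 (0.08), had a median difference of 0.25. These were bright in both fractions, which would hide a small share of such cells, so this source and a difference within the CD103− DCs cannot be told apart.

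Probe A_52_P549279, which the gene table did not name and the comparison therefore left out, had a difference of 5.90, the largest of the unnamed probes above background on both arrays and outside the patches, with a log2 signal of −1.90 in the CD103− cells. Of 7144 unnamed probes above background on either array, 364 were at least 2-fold higher and 442 lower.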

How the results depend on the processing

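Leaving out the patches and scaling on spike-in controls were chosen after the data were seen, the other alternatives before. No list median and no gene that the naming rule picked, of at least 1 in size, changed sign under any alternative run, and other genes were not run, and the 4 main lists kept their side of the random lists. With normexp the lower count was 1034 instead of 1626, of which 1023 genes were shared. The monocyte and macrophage median was −2.86 and the plasmacytoid DC median −0.59. Normexp started from median signals and added an offset of 50, which by construction draws differences of dim genes toward 0. The share of the change due to the offset was not tested. Over genes above background on both arrays the cDC1 median was 2.41, since genes with bounds drop out. As a mean over a gene's probes the plasmacytoid DC median was −1.40, and the cause was not tested. At 1.5-fold 1970 genes were higher, and at 3-fold 462 were higher and 1015 lower, by construction. Without patches the counts were 845 and 1442, and of the original calls 842 and 1434 remained. Of the list medians under alternatives, 331 were the same, 23 moved, 8 no longer stood apart and 1 newly did. Median scaling shifted the median of all genes by 0.13, and the higher share of calls at 2-fold ran from 33.3% to 44.0% (main 37.0%). Dim genes had only bounds where 1 array was not above background. The slide could not be a block because both arrays lay on 1 slide. No paired analysis was possible because each group had 1 array.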

Other observations

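All observations here were chosen after the values were seen, and no explanation was tested.

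In some families of related symbols, picked by eye and not tested for enrichment, the genes past 2-fold went 1 way, and in others they split, where 1626 of all 15067 genes were at least 2-fold lower; Klk1, Ms4a1, Ms4a7 and Adgre1 also stand in preset lists. All 14 measured genes of the tissue kallikrein family (Klk1 and the Klk1b genes), secreted serine proteases, were at least 2-fold lower in the CD103+ cells, from −5.09 to −2.42, although 3 lay in or beside patches and such near-identical paralogs can share signal on probes. Both measured Sirpb1 genes, activating relatives of Sirpa, were lower, with −5.28 and −4.94. Of 11 measured Ms4a genes, a family of membrane proteins that includes the gene of CD20, 6 were at least 2-fold lower and 0 higher, with 1 of the 11 in or beside a patch. Of 8 measured Cd300 genes, myeloid lipid receptors, 4 were at least 2-fold lower and 0 higher, and 1 of the 8 lay in or beside a patch. In the other direction, the 3 retrotransposon-derived Rtl8 genes were higher by 3.84 to 5.12, 1 of them from a spot in or beside a patch. Shared signal between related genes was not checked for the Sirpb1, Rtl8 or other families either, so their genes may not be separate observations. The Klrb1 family of NK-type lectins, with 1 of 4 genes in or beside a patch, split, with 3 genes higher, up to 4.54, and 1 lower, at −4.31, and so did the Adgre family, with 1 higher, at 2.13, and 2 lower, down to −4.80.

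Most measured genes of the progenitor and neutrophil lists were well above background in both fractions, such as S100a9, a call that dim genes can pass too. Gata2 and Mmp9 were not in the CD103+ cells. Of 16 neutrophil genes 13, and of 10 progenitor genes 8, had a difference below 0. The genes given next were picked from the few with a difference above 0, so they do not stand for their lists. Csf3r, the receptor for G-CSF, had a log2 signal of 5.91 in CD103+ and 5.72 in CD103− cells. Kit, the stem cell factor receptor, had 1.60 and 0.86, Cd34 had 2.82 and 1.53, and the neutrophil elastase gene Elane had 1.61 and 1.39.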
